A study of Mus musculus with 2 samples.

How the data were processed

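The analysis used 2 mouse libraries, 1 labelled WT and 1 labelled KC (a model with Pdx1-Cre), both with ganglion as the tissue. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was enriched on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit. Groups were taken from the sample titles, and the columns of the table were tied to the samples by the WT and KC at the start of their names. The number of animals behind each library is not given in the sources used here.

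Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, with genome build mm10. Their roles and the annotation release are not given in the sources used here. The deposited table holds an estimated count and an FPKM value per gene and library, per the file headers. The deposited estimated counts were not exactly whole, with no tolerance, in 7.85% of genes in WT and 7.62% in KC. The authors' FPKM values differed from the counts by one factor per library: the median FPKM per count was 1.0773 times higher in WT, the same as the ratio of the total counts. Whether the counting used strand is not stated, so overlapping and antisense genes cannot be separated. All per-sample columns of the table were used. The table lists 22063 genes, of which 21973 have identifiers in GENCODE vM21 (the same build) and 21573 are protein-coding there. Coordinates are from that annotation.

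Estimated counts were rounded to whole numbers and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.9949 for WT and 1.0051 for KC). Log2 ratios of KC over WT were taken from CPM with a prior count of 0.5. A gene was measured when it reached 1 CPM in at least 1 library, which 13503 genes did. With 1 library per genotype no test across replicates exists, so edgeR served for scaling only and no p-value was computed. Each ratio has an exact Clopper-Pearson 95% interval computed from the 2 counts, which covers counting error and leaves out variation between animals and dissections. Sequencing reads without molecular identifiers are not independent molecules, so the intervals are too narrow even for that. A gene was counted as higher or lower when its ratio was at least 2-fold and its interval excluded 1. A ratio against a library at 0 counts was computed against 3 counts in that library and is a lower bound for a count of 0; it leaves out the counting error of the other library, which the interval includes. Where a ratio is given for a gene with 1 to 3 counts in a library, its interval is given too. Other such genes are given by their counts, and no fold is given where both libraries had at most 3.

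Gene lists for 50 cell types and processes, 42 genes of interest, the rules for naming genes and the alternatives were fixed before the data were examined. A list was described by the median log2 ratio of its measured genes and by the percentile of that median among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. Genes are not replicates, so the percentile describes these libraries and is not a p-value. Lists with fewer than 5 measured genes have no percentile. A list's median also has a 95% range from 1000 Poisson draws of its counts. KEGG and GO process terms in the table with 15 to 300 measured genes were treated in the same way. A further 2 lists, of lymph node vessels and stroma and of immunoglobulin constant genes, were written after the data were seen. The genes named were the 12 highest and 12 lowest in KC by the bound of the counting interval nearest to 0 (unnamed gene models, pseudogenes, V, D and J segments and sex-linked genes left out), the 42 fixed genes, and up to 4 members of a list, those with the 2 highest and 2 lowest ratios among members with at least 30 counts over both libraries. Some genes that these rules select are not reported here. A symbol with several identifiers was taken at the one with most counts in the lists.

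The procedure was tested on simulated data. With counts drawn for 22063 genes from the mean of the WT and KC libraries and 200 genes changed, 100% of the 4-fold changes were counted in each direction, and 56% of the 2-fold higher and 38% of the 2-fold lower ones. Of unchanged measured genes 0.19% were counted, and 95.5% of their intervals held the true ratio. Of 300 lists of 20 genes drawn at random from the measured simulated genes, 7.0% lay in the top or bottom 2.5% of random lists. A list of 20 of the more abundant genes, with ratios raised by 0.5 on the log2 scale, lay at percentile 100. Neither result covers lists made up of low genes or of genes that vary together. The simulation holds counting noise only. The alternatives were DESeq2 1.42.0 size factors, total counts and upper-quartile scaling, a minimum of 5 CPM or of 1 count, a prior count of 5, the whole interval beyond 2-fold, means in place of medians, random lists without matching, and the authors' FPKM as log2(FPKM + 1). The FPKM alternative took genes with at least 1 FPKM in at least 1 library and used no counting interval, so its measured genes differ. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.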

Results

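Polyadenylated RNA was sequenced from 2 mouse libraries whose labels name the tissue as ganglion, 1 from a wild-type animal or pool (WT) and 1 from the KC model. KC mice are a model of early pancreatic cancer that carries Pdx1-Cre, which is active in the developing pancreas. The series set out to study how the change of acinar cells into duct-like cells and the growth of nerves into the pancreas bear on each other early in pancreatic cancer. The estimated counts summed to 15606927 in the WT library and 16812728 in the KC library, over 22063 genes. With 1 library per genotype there was no replicate check and no test, so every difference described is one between these 2 libraries. Intervals and floors cover counting error only. A count of 3, the limit that a count of 0 allows, stood for 0.192 CPM (counts scaled to library size) in the WT library and 0.178 CPM in the KC library.

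Genes of neurons lay near the floor in both libraries labelled ganglion, while genes of lymphocytes were among the most abundant. Th and Dbh, which make noradrenaline, the noradrenaline transporter gene Slc6a2, the neuropeptide gene Npy, Chat, which makes acetylcholine, and Vip had 0 counts in both libraries. Of 24 pan-neuronal genes, 8 had at most 3 counts in each library, and their median was 0.414 FPKM in WT and 0.152 FPKM in KC. Medians were 0.143 and 0.060 FPKM for 24 noradrenergic genes, 0.058 and 0.007 FPKM for 22 sensory neuron genes, and 0.056 and 0.110 FPKM for 10 cholinergic genes. Sox10, a glial transcription factor, had 1 count in WT and 3 in KC. B and plasma cell genes had medians of 128 FPKM in WT and 124 FPKM in KC, T and NK cell genes 64.3 and 65.1 FPKM, MHC class II genes 179 and 190 FPKM, and macrophage genes 33.3 and 29.4 FPKM. By FPKM, the kappa light chain gene Igkc ranked 2 in WT and 3 in KC, and Glycam1, a gene of high endothelial venules, ranked 5 and 6. Ighm, the IgM heavy chain gene, ranked 6 and 10, the MHC class II chaperone gene Cd74 ranked 7 and 5, and Ccl21a, a chemokine gene of lymphoid stroma, ranked 9 and 16. These 5 genes were picked after their ranks were seen. A list of 18 genes of lymph node vessels and stroma, written after the data were seen, had medians of 73.6 and 80.4 FPKM. Its log2 ratios had a median of -0.04 and a percentile of 14.14. Ccl21a has near-identical copies, so its count is uncertain.

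**Figure D1:**
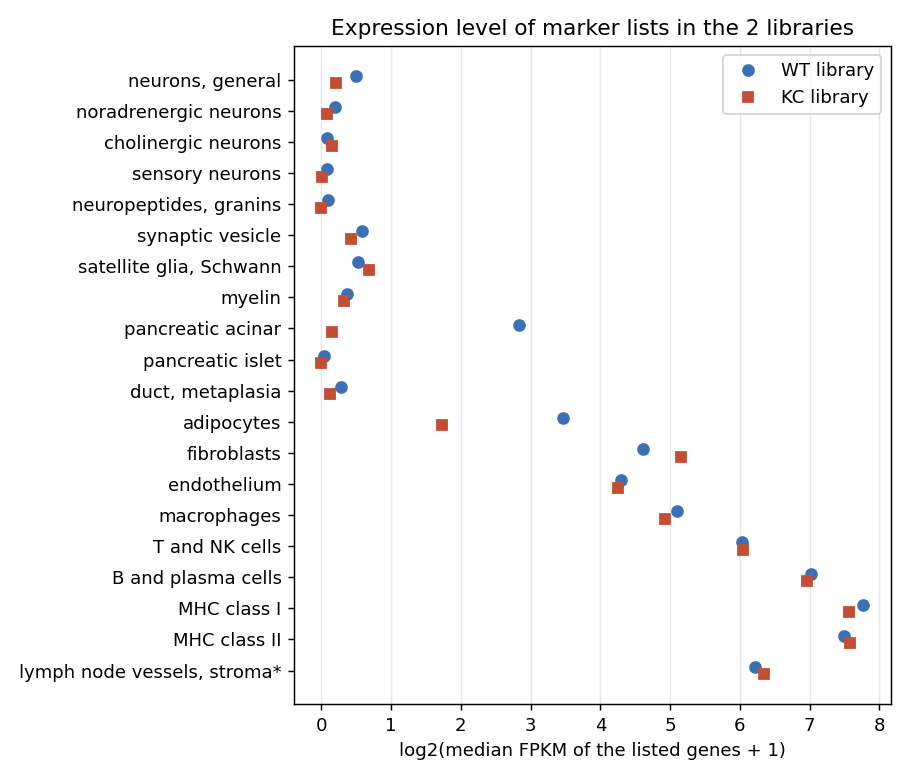
Median FPKM of each marker list in the WT library (circles) and the KC library (squares), plotted as log2(median + 1); the list with an asterisk was written after the data were seen. The neuron lists lie near 0 in both libraries (pan-neuronal genes 0.414 and 0.152 FPKM), and the B and plasma cell list lies at 128 and 124 FPKM.

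Most genes had close values in the WT and KC libraries. Among 13503 genes with at least 1 CPM in at least 1 library, the quartiles of the log2 ratios of KC over WT were -0.15 and 0.14. At least 2-fold higher values in KC, with a counting interval above 0, were found for 184 genes, and at least 2-fold lower values for 291. V, D and J segments of immunoglobulin and T-cell receptor genes made up 24 of the 184 and 56 of the 291. The 2 counts depended on the filter: 52 and 123 genes passed with a minimum of 5 CPM, and 51 and 135 had the whole counting interval beyond 2-fold. Pdx1, whose promoter drives Cre, had 0 counts in both libraries.

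Genes of pancreatic acinar cells, which secrete digestive enzymes, were far lower in the KC library. All 27 measured members of the acinar list had log2 ratios below 0, 24 of them at least 2-fold, with a median of -5.63 (percentile 0 among 10000 random lists matched on expression). With genes at 0 counts set to their bound, the median was -4.80, and with the authors' FPKM it was -2.89. Acinar genes also filled 10 of the 12 places for the genes lowest in KC, the extra amylase copies included. Prss2, a trypsinogen gene on chromosome 6 at 41521787 to 41525079 (mm10), had 351 counts in WT and 0 in KC, at least 127-fold lower against a floor of 3 counts (upper bound of the log2 interval -6.69). Rnase1, which encodes the pancreatic ribonuclease, had 137 counts and 0, at least 49.7-fold lower against that floor (upper bound -5.32). The pancreatic lipase gene Pnlip (534 and 6 counts) was 96.9-fold lower, and the elastase gene Cela2a (658 and 9 counts) 79.6-fold lower. Cpa1, a carboxypeptidase gene, had 389 counts in WT and 3 in KC, a log2 ratio of -6.91 (95% interval -9.43 to -5.58), and the trypsin gene Try5 had 248 and 1, a log2 ratio of -7.47 (interval -13.39 to -5.59). Amy2a5 was 77.2-fold lower (1703 and 23.6 estimated counts). Amy2a2, Amy2a3 and Amy2a4 had identical values of 378 estimated counts in WT and 0.33 in KC. These near-identical amylase copies are uncertain, as are the trypsin genes, which also share sequence. The transcription factor genes Bhlha15 (log2 ratio -0.33, interval -0.63 to -0.02) and Nr5a2 (-0.54, interval -0.95 to -0.14) had smaller differences. Acinar genes took 0.053% of counts in WT and 0.0032% in KC. Of 34 duct and metaplasia genes only 9 were measured, and 14 had at most 3 counts in each library. The 9 showed no such shift: 5 lay above 0 and 4 below, with a median of 0.02 (percentile 61.11; -0.22 and percentile 22.03 with no minimum beyond 1 count). Krt19, below the minimum of 1 CPM, had 11 and 2 counts, a log2 ratio of -2.31 (interval -5.80 to -0.39). Within that list Epcam had a log2 ratio of 0.25 (interval -0.16 to 0.67) and Spp1 one of -0.54 (interval -1.55 to 0.41). Ins2, the insulin gene, had 0 counts in both libraries.

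Adipocyte genes were lower in the KC library as well. All 20 measured members had log2 ratios below 0, 10 of them at least 2-fold, with a median of -1.03 (percentile 0), a mean of -1.80 and a median of -0.69 with the authors' FPKM. Adipoq, which encodes the fat hormone adiponectin, was 22.1-fold lower (284 and 14 counts), and Car3, a carbonic anhydrase of fat and muscle, 24.4-fold lower (1254 and 56 counts). Fasn and Scd1, enzymes of fatty acid synthesis found in many cells, had log2 ratios of -0.01 (interval -0.08 to 0.05) and -0.11 (interval -0.16 to -0.07). Pck1, the enzyme gene of gluconeogenesis and glyceroneogenesis, was among the 12 lowest genes, with 331 counts in WT and 3 in KC (log2 ratio -6.68, interval -9.19 to -5.35). Mesothelial genes, which mark the lining of the abdomen, had too few measured members for a percentile. All 4 lay below 0, from -3.81 for Upk3b (32 and 2 counts, interval -7.23 to -2.15) to -0.46 for Gas1, with a median of -0.82. In the liver, gut and kidney list, 3 of 4 measured members lay below 0, and Alb, which encodes albumin, had 119 and 31 counts, 4.18-fold lower.

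**Figure D2:**
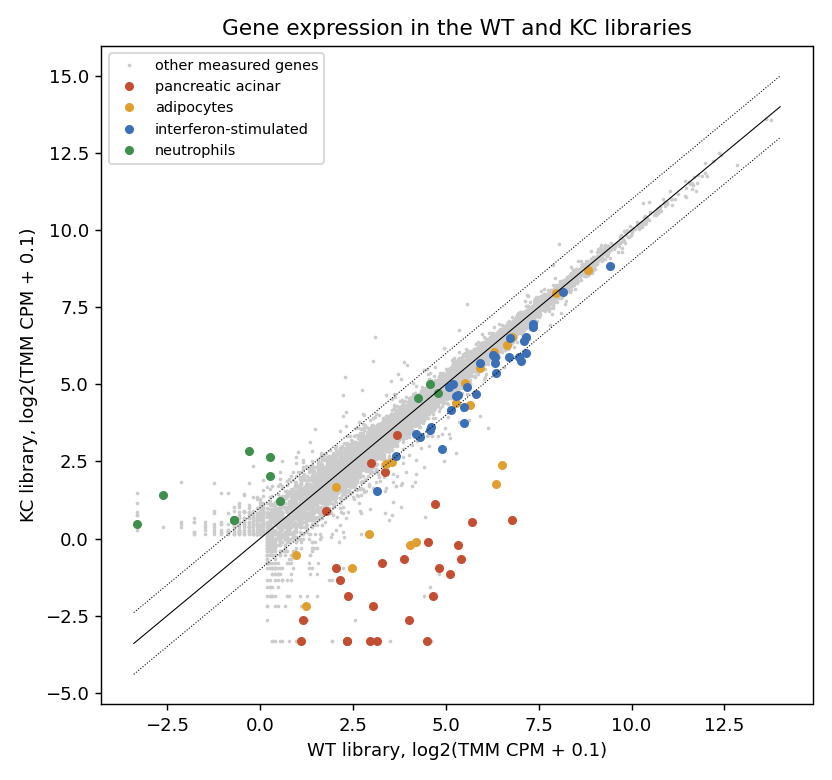
Each point is a gene with at least 1 CPM in at least 1 library, at its log2(TMM CPM + 0.1) in the WT library (horizontal) and the KC library (vertical); the solid line marks equal values and the dotted lines 2-fold differences. Acinar genes lie far below the line (24 of 27 at least 2-fold lower). Interferon-stimulated genes lie below it (32 of 32 below 0, 10 at least 2-fold lower), and 7 of 11 neutrophil genes lie above the upper dotted line.

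Interferon-stimulated genes, which respond to type I and II interferons, were lower in the KC library as a group. All 32 had log2 ratios below 0, 31 with a counting interval below 0 and 10 at least 2-fold lower, and the median was -0.75 (percentile 0). Ifit1 and Ifit3, antiviral genes, were 4.0-fold (459 and 125 counts) and 3.39-fold lower. Irf1, a transcription factor gene of the same response, had a log2 ratio of -0.15 (interval -0.21 to -0.09), and the RNA sensor gene Ifih1 one of -0.18 (interval -0.35 to 0.00). All 15 genes of MHC class I presentation were lower too, by less, with a median of -0.23 (percentile 0). B2m, the class I light chain gene, had a log2 ratio of -0.38 (interval -0.40 to -0.36) and Psmb8, an immunoproteasome gene, one of -0.09 (interval -0.15 to -0.04). Among T and NK cell genes, 18 of 26 lay below 0 (median -0.07, percentile 1.12). The percentile was 10.29 with the authors' FPKM and 7.22 among random lists without matching. The lowest were the NK cell genes Klrb1c (2.07-fold lower, 287 and 151 counts) and Ncr1 (log2 ratio -0.80, interval -1.30 to -0.32). Cd3e, a gene of the T-cell receptor complex, had a log2 ratio of -0.05 (interval -0.13 to 0.03). Macrophage genes had a median of -0.06 (percentile 4.19; -0.11 and percentile 0.38 with no minimum), with Fcgr1, an Fc receptor gene, at -0.98 (interval -1.36 to -0.61) and the scavenger receptor gene Cd163 at 0.94 (interval 0.55 to 1.34). Adgre1 had a log2 ratio of -0.22. B and plasma cell genes had a median of -0.01 (percentile 30.99) and MHC class II genes one of 0.01 (percentile 53.64). Ptprc, the pan-leukocyte gene, was at 0.08 (interval 0.04 to 0.11).

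Genes of dividing cells were slightly lower in KC: 24 of 25 cell cycle genes lay below 0, with a median of -0.25 (percentile 0). Aurkb, a mitotic kinase gene, was at -0.61 (interval -0.84 to -0.38), and the proliferation marker Mki67 at -0.25 (interval -0.35 to -0.14). Plk1 was at 0.03 (interval -0.17 to 0.23). Genes of the unfolded protein response had a median of -0.21 (percentile 0), with the chaperone gene Hsp90b1 at -0.45 (interval -0.48 to -0.41). Small shifts downward were also found for 76 ribosomal protein genes (median -0.10, percentile 0) and 42 oxidative phosphorylation genes (median -0.07, percentile 0.26, or 3.18 among random lists without matching).

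Neutrophil genes were higher in the KC library, most of them at low counts. Of 11 measured members, 10 lay above 0 and 7 were at least 2-fold higher, with a median of 1.41 (percentile 100). The median was 0.45 with a minimum of 5 CPM and 0.87 with the authors' FPKM. S100a9, a calcium-binding protein gene of neutrophils, had 11 counts in WT and 120 in KC, a log2 ratio of 3.27 (interval 2.44 to 4.37), and its partner S100a8 was 3.68-fold higher (17 and 68 counts). Lcn2, which encodes the iron-scavenging protein lipocalin 2, was 5.57-fold higher (17 and 103 counts). Mpo and Elane, granule enzyme genes of immature neutrophils, were at or under the floor in WT. Mpo had 1 count in WT and 43 in KC, a log2 ratio of 4.76 (interval 2.75 to 10.64), and Elane had 0 and 22, at least 6.74-fold higher against a floor of 3 counts (lower bound of the log2 interval 2.33). Cxcr2, the receptor gene for neutrophil chemokines, was at -0.09 (interval -0.28 to 0.11), and Csf3r at 0.31 (interval 0.09 to 0.53). Genes of red blood cells were higher as well, with 7 of 7 above 0, 5 at least 2-fold and a median of 1.21 (percentile 100). Alas2, an enzyme gene of heme synthesis in erythroid cells, was 6.89-fold higher (6 and 45 counts), and the globin gene Hba-a1, which shares reads with Hba-a2, 3.03-fold. Fech and Bpgm were at 0.10 (interval -0.07 to 0.26) and 0.11 (interval -0.11 to 0.34).

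Chemokine genes were also among the 12 highest in KC. Ccl20, which attracts CCR6-bearing lymphocytes and lies on chromosome 1 at 83116766 to 83119167, had 2 counts in WT and 59 in KC, a log2 ratio of 4.46 (interval 2.84 to 7.84). Cxcl5, a neutrophil chemokine gene, had 0 and 19 counts, at least 5.82-fold higher against that floor (lower bound 2.10). Ighe, the IgE heavy chain constant gene, was 7.92-fold higher (74 and 638 counts), and the phosphate hormone gene Fgf23 10.5-fold (5 and 57 counts). Over the cytokine and chemokine list, 22 of 34 measured genes lay above 0 and 12 below (median 0.20, percentile 100). Ccl7, a monocyte chemokine gene, was 3.37-fold higher (9 and 33 counts). The interferon-induced chemokine genes Cxcl9 and Cxcl10 went the other way, with log2 ratios of -1.26 (interval -1.37 to -1.15) and -0.99 (interval -1.20 to -0.78). Ccl2 was at -0.22 (interval -0.85 to 0.41) and Cxcl12 at -0.07. Il6 had 4 and 2 counts. Complement and acute-phase genes had a median of 0.19 (percentile 100), and 12 of 17 lay above 0. Saa3, an acute-phase gene, was 3.0-fold higher (15 and 49 counts), while Cfd, a complement gene made by fat cells that is also in the adipocyte list, was 17.8-fold lower (1406 and 86 counts). The remaining 4 of the 12 highest genes and 1 of the 12 lowest are uncertain. Fam205a3 (0 and 28.7 estimated counts), Lilrb4a (0 and 27.3) and Samd11 (1.02 and 19.5) had values that are not whole, so reads may be shared with other genes. Pakap had 12.4 and 85.2 in one gene model and 1691 and 1815 in another of the same name. Fam220a had 173 and 0 in one gene model and 192 and 402 in a second of the same name.

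Genes of connective tissue were modestly higher in the KC library. Of 39 extracellular matrix genes, 34 lay above 0 and 30 had a counting interval above 0, with a median of 0.38 (percentile 100). Ccn1, a matricellular protein gene, was 2.51-fold higher (68 and 186 counts) and Mmp3, a matrix protease gene, 2.01-fold (48 and 105 counts). Fibroblast genes had a median of 0.34 (percentile 100), with 15 of 18 above 0. The collagen gene Col3a1 was at 0.98 (interval 0.92 to 1.03), Col1a1 at 0.57 (interval 0.50 to 0.65) and Cd34 at -0.23 (interval -0.34 to -0.12). Pericyte and smooth muscle genes had a median of 0.20 (percentile 99.99) and a mean of 0.13 (percentile 90.23), with Pdgfrb at 0.45 (interval 0.31 to 0.60). Endothelial genes did not stand apart (median -0.05, percentile 13.16), and Pecam1 was at -0.11.

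**Figure D3:**
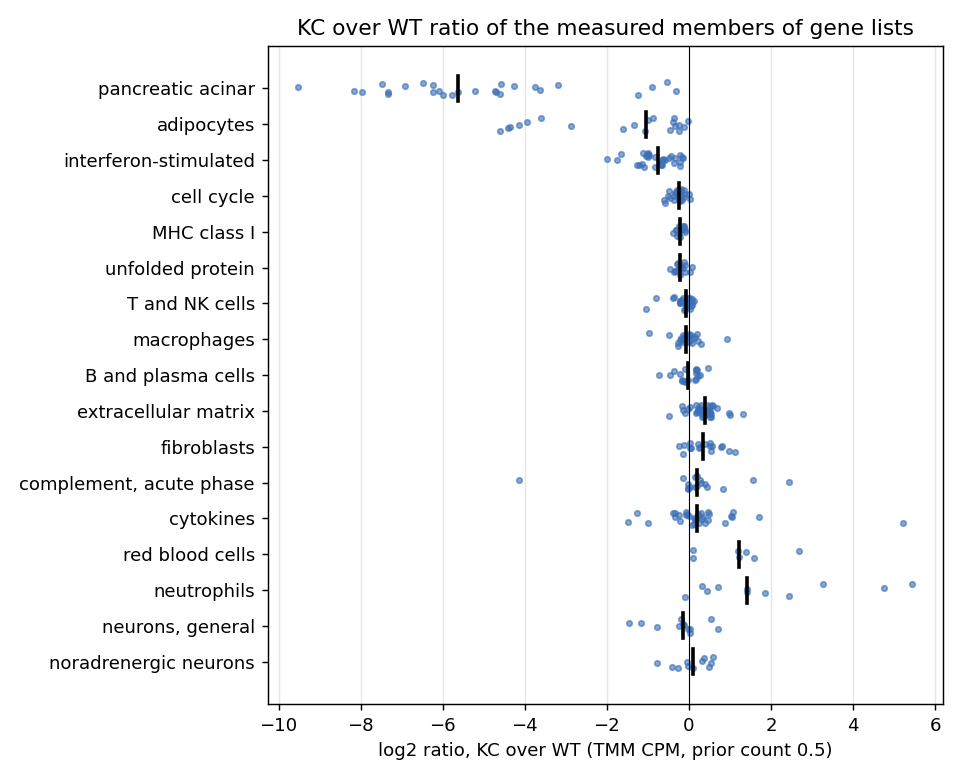
Log2 ratios of KC over WT of the measured genes of 17 lists, 1 point per gene, with a vertical bar at each list's median. Acinar genes have the lowest median (-5.63), followed by adipocyte (-1.03) and interferon-stimulated genes (-0.75), and neutrophil genes the highest (1.41); the pan-neuronal list lies at -0.14.

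Genes of neurons, the cells the tissue label leads to, were measured at the low levels given above, and their lists depended on the minimum count. The pan-neuronal list had a median of -0.14 (percentile 19.41; 0.04 with a minimum of 5 CPM and 0.06 with FPKM), with 8 of 12 measured members below 0. Stmn2, a microtubule regulator gene of growing axons, was at 0.53 (101 and 159 counts, interval 0.16 to 0.91), and Syn1, a synaptic vesicle gene, at -1.45 (26 and 10 counts, interval -2.72 to -0.40). Tubb3, the neuronal tubulin gene, had 37 and 34 counts, Prph 17 and 8, and Snap25 13 and 0. Thy1, also a T-cell gene, is a member of this list with 4151 and 4629 counts. Noradrenergic genes had a median of 0.10 (percentile 85.02) over the 11 of 24 that were measured, and cholinergic genes 0.01 (percentile 54.94) over 5 of 10. Th, Dbh, Slc6a2, Npy and Chat, at 0 counts, did not enter these medians. Enteric neuron genes had a median of 0.19 (percentile 87.79) over 6 of 12, and sensory neuron genes 0.03 (percentile 63.04). Only 5 of the 22 sensory genes were measured. Most of that list's 2804 and 3186 counts came from Runx3 (1400 and 1598) and Runx1 (1010 and 1185), transcription factor genes not particular to neurons. In the noradrenergic list, Gch1, which serves tetrahydrobiopterin synthesis in many cells, was at 0.59 (interval 0.30 to 0.88), and Snap91 at -0.77 (interval -1.45 to -0.12). Synaptic vesicle genes lay at -0.14 (percentile 12.09) and neuropeptide and granin genes, 8 of 30 measured, at 0.01 (percentile 55.5). Transmitter receptor genes, 14 of 40 measured, lay at 0.08 (percentile 81.57). Spinal cord and brain genes, 5 of 14 measured, lay at -0.41 (percentile 3.5, or 0.61 among random lists without matching). With a minimum of 5 CPM the noradrenergic list lay at 0.34 (percentile 99.88), again without Th, Dbh, Slc6a2 or Npy. With no minimum beyond 1 count the synaptic vesicle list lay at -0.28 (percentile 2.19), and its median of -0.14 was at percentile 0.66 among random lists without matching. No minimum also turned the medians of the transmitter receptor (-0.20), sensory (-0.11), enteric (-0.17) and neuropeptide lists (-0.57) below 0, and the mean of the transmitter receptor list was -0.19. Calca, Tac1, Trpv1 and Gap43 had 1 count in WT and 0 in KC, and Rbfox3 had 1 and 3, too few for a fold. Gal had 4 and 2 counts.

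The satellite glia and Schwann cell list had a median of 0.36 (percentile 99.88), which was 0.17 (percentile 95.25) with the authors' FPKM and 0.19 with a minimum of 5 CPM. Its highest members, Ncam1 (0.83, interval 0.05 to 1.68) and L1cam (0.68, interval 0.45 to 0.93), encode adhesion molecules of several cell types, and Sox10 was at the floor. Myelin genes as a list had a median of -0.10 (percentile 19.46). Axon guidance genes lay at 0.11 (percentile 99.8; percentile 91.54 for the mean), with 35 of 52 above 0. Slit2, a secreted guidance cue, was 2.24-fold higher (30 and 73 counts), and the Eph receptor gene Ephb2 at -0.99 (interval -1.57 to -0.46). Voltage-gated channel genes lay at 0.20 (percentile 99.84; percentile 96.99 for the mean), with 21 of 29 above 0. Kcnab1 was at 0.99 (interval 0.10 to 2.0) and Scn8a at -1.09 (interval -2.31 to -0.02). Neuron genes lay near the floor, and fibroblast and matrix genes were higher in KC. The channel and axon guidance lists can therefore not be assigned to neurons, and which cells their values came from was not tested. Nerve injury genes had a median of -0.01 (percentile 47.26), but of -0.30 (percentile 0.55) with no minimum beyond 1 count. Socs3, a brake on cytokine signaling, was at 0.50 (interval 0.39 to 0.62), Atf3 at 0.20 (interval -0.29 to 0.70), and Sprr1a had 0 counts in both. Repair Schwann cell genes lay at -0.14 (percentile 14.43) and neurotrophic factor and receptor genes at 0.05 (percentile 78.36).

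Genes that report MAPK signaling did not stand apart in the KC library (median 0.03, percentile 69.21). Dusp6, a phosphatase gene induced by ERK, was at -0.03 (interval -0.15 to 0.08), Spry2, a feedback inhibitor gene, at 0.68 (interval 0.19 to 1.20), and Fos at 0.30 (interval -0.17 to 0.78). Immediate early and stress genes had a median of -0.05 (percentile 14.79), with the heat shock genes Hspa1a (-1.33, interval -1.89 to -0.81) and Hspa1b (-1.37, interval -1.82 to -0.95), which share sequence, at the low end. The remaining lists with at least 5 measured genes were hypoxia and glycolysis (-0.03, percentile 22.17), skeletal muscle (0.03, percentile 60.18; -0.12 with no minimum), histone (0.12, percentile 91.37) and mitochondrially encoded genes (-0.07, percentile 5.85). The histone list lay at -0.38 (percentile 9.87) with no minimum and had a mean of -0.19 (percentile 21.38). Too few genes were measured for a percentile in the mast cell (3 genes), islet (3), adrenal cortex (4) and chromaffin cell (2) lists. Their medians were 0.31, -0.12, 0.30 and 0.49. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 counts in both libraries and Kdm5d had 1 in each. Of the 43 lists with a percentile, 10 lay in the top 2.5% of the random lists and 9 in the bottom 2.5%.

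Pathway terms that the authors' table attaches to each gene gave related groups. Of 318 KEGG terms, 38 lay in the top 2.5% and 41 in the bottom 2.5%, and of 1624 GO process terms 173 and 93. Among GO terms, the 51 genes of the cellular response to interferon-beta had a median of -0.37, the 45 genes of negative regulation of viral genome replication -0.24, and the 19 genes of protein refolding -0.36, each at percentile 0. Collagen fibril organization (41 genes) had a median of 0.24 and neutrophil chemotaxis (60 genes) 0.18, each at percentile 100. Among KEGG terms, axon guidance (153 genes) and chemokine signaling (159 genes) had medians of 0.07 at percentile 100. The axon guidance term, like the list above, does not show which cells its values came from. DNA replication (36 genes) lay at -0.16 and antigen processing and presentation (65 genes) at -0.11, both at percentile 0. KEGG terms such as asthma (97 genes, median -0.27) held many immunoglobulin segments.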

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

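The exclusions of immunoglobulin segments and of the acinar and adipocyte lists, and the 2 alternatives for KEGG terms, were chosen after the data were seen. Under DESeq2, total-count and upper-quartile scaling, a prior count of 5 and no minimum beyond 1 count, the number of genes at least 2-fold higher in KC ran from 133 to 255 and the number lower from 254 to 427. They were 52 and 123 with a minimum of 5 CPM, which removes low genes, and 51 and 135 with the whole counting interval beyond 2-fold. With the authors' FPKM they were 62 and 153. There the pseudocount shrinks low genes, the minimum was 1 FPKM in at least 1 library, and no counting interval was required. The part of each was not separated. Without V, D and J segments they were 160 and 235, and without the acinar and adipocyte lists 184 and 257. Scaling moved the median of all genes by at most 0.0147 on the log2 scale. The number of lists in the top or bottom 2.5% of random lists was 19 and ran from 16 to 24 over the alternatives. The glia list and the T and NK cell list left these tails with FPKM, the axon guidance, channel and pericyte lists as means, and the T and NK cell and oxidative phosphorylation lists among random lists without matching. The nerve injury, synaptic vesicle, macrophage, mesothelial (-1.19) and liver, gut and kidney lists (-1.21) entered them with no minimum, the noradrenergic list with a minimum of 5 CPM, and the synaptic vesicle and spinal cord lists without matching. The 79 KEGG terms found there became 80 with total counts and 79 with a prior count of 5. Of the leading lists, the neutrophil median moved from 1.41 to 0.45 with a minimum of 5 CPM and to 0.87 with FPKM, the interferon median from -0.75 to -0.67 with FPKM, and the adipocyte median from -1.03 to -0.69 with FPKM and to -1.80 as a mean. The acinar median moved from -5.63 to -4.73 with no minimum, -4.14 with a prior count of 5 and -2.89 with FPKM. Filters and pseudocounts act on low genes by construction; for the mean of the adipocyte list the cause was not tested. Over all 43 lists, 266 medians or means stayed within the counting range of the list's median and 25 left it. Single genes were checked for 226 measured genes, those selected by the naming rules: 852 values stayed within the counting interval and 52 left it. No list in those tails in the main setting changed sign under the alternatives run for it. Nor did any of the 226 genes whose interval excluded 0. The FPKM pseudocount of 0.1, planned for a table without counts, and leaving out columns of a library did not apply, and upper-quartile scaling was run for the gene counts only. Several lists outside the tails, the pan-neuronal list among them, did change sign. At this depth a gene at 1 CPM is detected in either library, but ratios of low neuron and neutrophil genes have wide counting intervals.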

Other observations

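All tests below were chosen after the results they bear on were seen. Immunoglobulin classes differed between the 2 libraries. Ighm, the IgM gene, was lower in KC (113998 and 75319 counts, log2 ratio -0.72, interval -0.73 to -0.71), while Ighg1, the IgG1 gene, was 2.83-fold higher (4092 and 12589 counts) and Ighe 7.92-fold higher. Over 13 constant genes the median was -0.01 (percentile 44.22). Of 107 V, D and J segments with at least 100 counts over both libraries, 19 were at least 2-fold higher in KC and 36 lower, although the segments together took 0.25% of counts in each library. Similar segments share reads, so single segments are uncertain.

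Neuron genes near the floor in both libraries labelled ganglion are the pattern a reader would most want to check. The depth was enough to show neuron genes at 1 CPM, since 3 counts stand for 0.192 CPM in the shallower library. That limit follows from the library total alone and leaves lower levels open. Missing gene models are argued against, as 24 of 24 pan-neuronal genes had a count in either library. A candidate explanation is that lymphoid tissue made up most of both samples: the B and plasma cell, T and NK cell and MHC class II lists, fixed before the data were examined, had medians at percentile 94.9 of all genes by FPKM or above in both libraries, against at most 39.9 for the pan-neuronal list. Th, Dbh, Slc6a2, Npy, Chat and Vip, at 0 counts in both libraries, argue against a sizeable share of noradrenergic or cholinergic ganglion neurons. Some neuron genes, such as Stmn2 (101 and 159 counts), were detected. Whether lymphoid tissue was dissected in place of a ganglion or with a small part of one is not decided by these tables.

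Acinar and adipocyte genes were lower in KC. Scaling is argued against, because 3 other scalings moved the median of all genes by at most 0.0147, and so are reads shared between paralogs, because 11 acinar genes outside the amylase, protease and lipase families had a median log2 ratio of -4.58. More pancreas and fat tissue in the WT sample may account for it. The mesothelial genes, another tissue at the surface of the organ, had a median of -0.82, with 3 of 4 counting intervals below 0. That support is weak. Upk3b had 32 and 2 counts, but the more abundant Gpm6a (357 and 252) and Gas1 (198 and 157) kept most of theirs in KC. The interval of Lrrn4 (-2.25 to 0.06) held 0. The insulin gene Ins2 at 0 counts in both libraries gives no sign of islet tissue. Loss of acinar transcripts with the KC genotype stays open and untested, since 1 library per genotype holds both genotype and any difference in dissection.

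Interferon-stimulated genes were lower in KC. A general loss of lymphocytes or macrophages is argued against as the cause, since the lowest median of the macrophage, T and NK, and B and plasma cell lists was -0.071. Fewer cells of a subset stay open. The NK cell genes Klrb1c (-1.05) and Ncr1 (-0.80) were lower by about as much as the interferon list. They were among the lowest members of the T and NK cell list. Prf1, a gene of cytotoxic cells in the T and NK cell list, was at 0.09 (interval -0.11 to 0.28), and macrophage genes went both ways (10 above 0 and 14 below). Library scaling is argued against by an interferon median of at most -0.739 over the scalings, and a few abundant members by a median of -0.989 for the 16 least abundant ones. A difference in interferon exposure between the animals, whether from genotype, infection or housing, may remain and was not tested, with 1 library per genotype.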
